A study of Drosophila melanogaster with 36 samples.

How the data were processed

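Gene expression was measured in wing discs, the larval tissue that gives rise to the adult wing and notum, from 12 selected lines of Drosophila melanogaster, with 3 arrays per line and 36 arrays in all. Per the labels' protocols, total RNA was extracted from tubes of 100 discs, biotin-labelled complementary RNA was made from 5 µg of it, and each sample was hybridised to its own Affymetrix array. The deposited values are MAS5 signals, per the submitters' processing notes, with the version of that program not given in the sources used here. They are linear array intensity values as deposited by the authors, one per probe set and array, without logarithm and without detection calls. The values showed that each array had been scaled to 1 common level, because the trimmed mean between the 2nd and the 98th percentile was 2500.1 on every array. Signals ranged from 0.3 to 166060, and array medians from 239.7 to 430.1. The number of arrays limits the precision of every comparison.

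The deposited table held 18952 probe sets, of which 183 were controls and were left out. The remaining 18769 signals per array were taken to log2 with no pseudocount, since none was 0. Probe sets whose mean log2 value over the 36 arrays was below that of the median probe set, a signal of 259.72, were left out, and 9385 were tested. Gene symbols came from a table of the array platform's annotation, and were compared through gene identifiers with a gene table of the Drosophila assembly Release 6 plus ISO1 MT, which changed 0 symbols and gave the order of genes along chromosomes. That platform table gave 1 symbol to 13647 probe sets, several to 402 and none to 4720, and 13544 of the first kind were found in the gene table. Among the tested probe sets, 7867 had 1 symbol, 235 several and 1283 none. No gene was named from a probe set with several symbols.

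Arrays were grouped by line from the sample titles. Lines H and L are the Massachusetts (MA) founders, A1 to D1 and A2 to D2 are the high and low lines reselected from H by L hybrid populations, and the California (CA) high and low lines come from a separate population. Every array correlated more closely with the other arrays of its own line than with the rest, and no 2 arrays held identical values. The numbers inside the titles fall in separate runs, 1 for the reselected lines and 1 for H, L and both CA lines. Both lines of each pair lie in the same run, so a batch that follows these runs cannot produce a difference within a pair, but it would enter the position of reselected lines between the founders, which lie in the other run. In every pair the high line has the lower numbers. Within a pair, an effect of that order could therefore not be told apart from the direction of selection. The CA pair has the same order, yet it had the founder sign at 50.3% of the 2106 probe sets called between H and L. Of the concordant MA probe sets also called in CA, 39 had the same sign and 36 the opposite. These values argue against an order effect alike in all pairs, CA included, but not against one in MA pairs alone. The labels do not say that the 3 arrays of a line came from separate cultures, so p-values over arrays measure only the spread between these samples.

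Each high line was compared with the low line of its pair in R 4.3.3 with limma 3.58.1, with 1 mean per line, all 36 arrays in the model, an intensity trend in the variance and 24 residual degrees of freedom (prior 6.34). Probe sets with a Benjamini-Hochberg adjusted p below 0.05 were called. A concordant probe set was called with the same sign in all 5 MA pairs. The MA difference over line pairs was tested by limma on the 10 line means with the line pair as a block, since the labels say that both lines of a letter came from 1 hybrid population, and here the line is the replicate. This reason does not cover H and L. They are the parents of the reselected lines, so their pair counts as a replicate here but is not independent of the others. The difference between the CA pair and the mean of the MA pairs was a contrast in the model of 36 arrays. Errors are the SD over lines or pairs, or the standard error (SE) from the model, as stated. All p-values are two-sided except those from random draws of genes, which are one-sided. Other tests were exact permutations of the 8 reselected lines, exact sign flips of 4 pairs, and 1000 random draws of genes for gene order.

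For gene lists, limma's camera was run with a preset correlation of 0.01, on the MA line means and on the CA contrast, with Benjamini-Hochberg adjustment over 31 lists. Each gene was represented by its tested probe set of highest mean signal, and a list needed 5 measured members. The lists covered the Hedgehog, Dpp, Wingless, Notch, EGFR, Hippo and insulin pathways, vein and wing identity genes, cell cycle, ribosomal, mitochondrial, ecdysone, cuticle, matrix, detoxification, immune, heat shock and apoptosis genes, dosage compensation, and markers of other tissues. The lists, the comparisons, the filter and the rule for named genes were fixed before the data were examined. How older names in a list were matched to current symbols was settled later, after list results under earlier matching had been seen: a listed name that is not itself a current symbol was followed through the gene table's synonyms, with 1 exclusion, where the synonym belonged to an unrelated gene. Delta, written Dl in the Notch and vein lists, was not matched in this way and is missing from both. Other listed names also matched no probe set. The Wingless list matched 12 genes, the EGFR list 17 and the cell cycle list 32, each fewer than were listed, so these lists cover only part of their pathways.

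Genes were named by rule, from probe sets with 1 symbol. For concordant probe sets these were the 15 higher and 15 lower in the high lines with the largest mean difference, and for the MA difference over pairs the 10 and 10 with the largest difference and the same sign in 5 pairs. For the CA pair the rule took the 12 and 12 with the largest difference and no overlap between arrays, for the difference between CA and MA 5 and 5, and for each MA pair 3 and 3, again with no overlap between arrays. In each list, up to 4 called members per comparison were named, or concordant ones where no MA member was called. Other genes named were chosen after their values were seen, and the text says so.

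The procedures were tested on simulated data built from the observed spread between arrays, and for the MA test over line pairs also that between lines, with changes placed in 67 probe sets for 1.5-fold, 67 for 2-fold and 66 for 4-fold, among 9385. For 1 line pair, 53.7% of 1.5-fold, 85.1% of 2-fold and 98.5% of 4-fold changes were recovered, and 6% of calls were false. The simulated concordant calls recovered 38.8%, 79.1% and 97% of changes of these sizes, the difference between CA and MA 50.7%, 82.1% and 97% with 6.7% false calls, and the MA difference over line pairs 49.3%, 89.6% and 97% with 6% false calls. The false shares for 1 pair and for CA against MA hold for array noise only and say nothing of differences between lines, where 219 to 793 probe sets were called with an MA pair in the place of CA. Alternatives covered a pseudocount, other filters, quantile normalization, centring each array on its median, no intensity trend, replicate number as a block, each array left out, each MA pair left out, other thresholds, each pair fitted alone, arrays in place of line means, and other set tests. No sample or column was left out of the comparisons.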

Results

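Wing discs were taken 6.2 h before pupariation, at 20 °C, from lines selected in opposite directions for wing shape. Founders H and L came from a Massachusetts (MA) population after 20 generations of selection. Lines A1 to D1 (high) and A2 to D2 (low) were reselected from H by L hybrids after 34 generations of mixing, with 25 generations of selection and 10 of inbreeding. A high and a low line from a separate California (CA) population completed the 12 lines. All differences are log2 high minus low, so 1 unit is 2-fold, and n is 3 arrays per line unless another n is given. Each of the 36 arrays correlated more closely with its own line (mean r from 0.945 to 0.958) than with other lines (0.939 to 0.949). The first 2 principal components held 15.9% and 11.8% of the variance. Of 9385 probe sets tested, 2106 were called between H and L.

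Across the 5 MA pairs, the chemosensory receptor gene Ir76a rose by 3.93 ± 1.01 (mean ± SD over 5 pairs, adjusted p = 0.000737), from a signal of 120 ± 57 in low lines to 1536 ± 485 in high lines. CG32017 rose by 3.46 ± 0.64 (adjusted p = 0.000179), with line B1 standing apart from the other high lines. CG10359 rose by 2.13 ± 0.08 (adjusted p = 1.4e-06), from 2832 ± 169 to 12340 ± 554. The dosage compensation gene msl-3 rose by 2.00 ± 0.20 (adjusted p = 4.08e-05), from 1307 ± 198 to 5124 ± 360, and its second probe set by 1.45 ± 0.24. Among lower genes, the P450 gene Cyp6a17 fell by 3.53 ± 1.21 (adjusted p = 0.00257), from 1335 ± 732 to 114.2 ± 64.2, with line D2 apart from the other low lines. The glutathione S-transferase gene GstO3 fell by 1.84 ± 0.21 (adjusted p = 4.08e-05), from 32250 ± 1300 to 9096 ± 1280. Of these genes only msl-3 had a second tested probe set. For the others, sequence differences under the probes could not be told apart from changed expression.

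**Figure D1:**
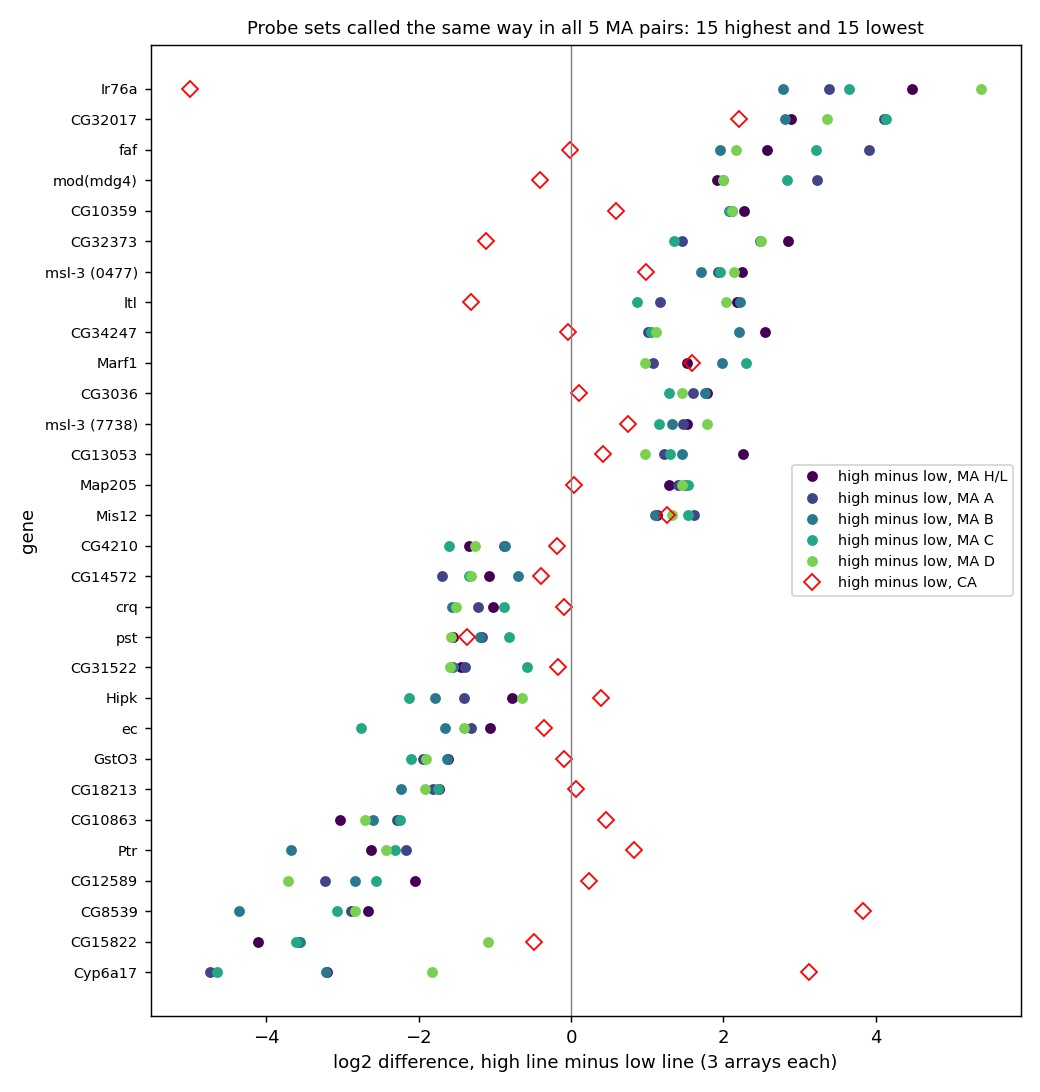
Log2 high minus low of the 30 named concordant probe sets, with 1 dot per MA pair and a red diamond for the CA pair. Ir76a had an MA mean of 3.93 and a CA value of -5.00, and GstO3 -1.84 and -0.09.

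Further genes rose in all 5 pairs. The microtubule-associated gene Map205 rose by 1.43 ± 0.10 (adjusted p = 1.3e-05) and the kinetochore gene Mis12 by 1.34 ± 0.23. CG3036 rose by 1.57 ± 0.21, Marf1 by 1.57 ± 0.57, CG32373 by 2.12 ± 0.68, ltl by 1.69 ± 0.63, CG34247 by 1.58 ± 0.73 and CG13053 by 1.44 ± 0.49. The ubiquitin protease gene faf rose by 2.76 ± 0.80 on 1 probe set (adjusted p = 0.00183), while its other probe sets gave 0.06 and -0.18. For mod(mdg4), a chromatin gene with many isoforms, 22 probe sets were tested and 3 were concordant and higher: 2.39 ± 0.60 (adjusted p = 0.000991), 0.92 ± 0.25 and 0.91 ± 0.12. Over line pairs, 4 more of its probe sets were called higher (0.22 to 0.49) and 3 lower (-0.62, -0.50 and -0.41), and the brightest gave -0.02. Called over line pairs but not within every pair were the serpin gene Spn47C (2.97 ± 1.54, adjusted p = 0.0121, pair values 4.75, 0.63, 2.68, 3.82 and 2.98) and the P450 gene Cyp310a1 (1.61 ± 0.53, adjusted p = 0.00255). Their largest adjusted p within a pair was 0.586 (pair A) and 0.155 (pair C, difference 0.82). Errors here are SD over 5 pairs.

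Other genes fell in all 5 pairs: CG8539 (-3.17 ± 0.68, adjusted p = 0.000407), CG12589 (-2.88 ± 0.64), CG10863 (-2.57 ± 0.32, adjusted p = 9.53e-05) and CG18213 (-1.89 ± 0.20). CG15822 (-3.19 ± 1.20), the patched-related gene Ptr (-2.64 ± 0.61) and CG31522 (-1.31 ± 0.42) also fell. Each of these 3 had 1 high line apart from the others. The kinase gene Hipk fell by 1.35 ± 0.63 (adjusted p = 0.00847). So did pst (-1.26 ± 0.31, adjusted p = 0.000655) and the hemocyte receptor gene crq (-1.24 ± 0.30, adjusted p = 0.000939). A probe set of ec fell by 1.64 ± 0.66 (adjusted p = 0.00695), and the others of that gene gave -0.64 (adjusted p = 0.0417) and -0.07. CG14572 (-1.22 ± 0.37) and CG4210 (-1.19 ± 0.31) also fell. CG31676 (-2.33 ± 0.73, adjusted p = 0.00222) and the ecdysone-induced receptor gene Hr3 (-1.66 ± 0.79, adjusted p = 0.01) were lower in 5 pairs and called over line pairs, but not called within every pair (largest adjusted p = 0.146 between H and L and 0.233 in pair C). Ir76a, faf and mod(mdg4) in low lines, and Cyp6a17, CG8539, CG12589, Ptr, ec and CG31676 in high lines, had mean signals from 109.2 to 230.9, under the filter level of 259.72 and without detection calls. CG15822 averaged 423.9 in high lines, with D1 at a log2 signal of 10.33. Its other high lines lay at 7.05 to 7.88, also under that level. The size of these differences is therefore less certain than their sign. In all, 175 probe sets were concordant in the 5 pairs, 96 higher and 79 lower in high lines. Of these, 151 had 1 symbol and covered 148 genes, 3 had several symbols and 21 had none. Tested over line pairs, 909 were called, 462 higher and 447 lower, and 871 of them had the same sign in 5 pairs. With each array centred on its median, 40.8% of the calls over line pairs were higher, against 50.8%. The founders are the parents of the reselected lines, so their pair is not independent of the other 4. Without the founder pair 369 were called over the 4 reselected pairs, 580 without pair A and 478 without pair D, and the concordant count was 267 without pair C.

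Within single MA pairs, the P450 gene Cyp6g1 rose by 5.21 between L and H (SE 0.55, adjusted p = 1.57e-08), with 1.74, 1.72, -2.44 and 3.29 in pairs A, B, C and D. Rnf11 fell by 6.73 there (SE 0.35, adjusted p = 1.52e-15), with 0.05, -2.35, 0.29 and -2.83 in the same order. Its second probe set gave -3.85 between L and H, and 0.03, -0.78, 0.44 and -1.07 in those pairs. For CG1894 the 5 values were -5.33, 0.69, -1.33, -4 and -4.84, for CG12129 -4.67, 0.28, -5.80, -4.41 and -5.09, and for CG31436 2.86, -4.28, 0.68, 3.15 and -1.09 (SE 0.44, 0.67 and 0.41). CG12129 had a mean signal of 153.8 ± 48.8 in high lines, under the filter level of 259.72, so the size of its differences is less certain. GstE11 gave 4.18, -0.16, 1.90, 4.05 and 4.37 (SE 0.34), CG10809 -3.60, -4.19, -4.39, 0.20 and -2.10 (SE 0.49), and se, a glutathione S-transferase gene, 1.05, 1.94, 2.68, 1.39 and 0.87 (SE 0.53). Between H and L, 1019 probe sets were higher and 1087 lower in H. The counts were 728 and 748 in pair A, 591 and 598 in B, 638 and 691 in C, and 467 and 476 in D. Each array centred on its median moved the median H minus L difference from 0.04 to -0.20 and the higher share of its calls from 48.4% to 11.2%, and put the median CA minus H and L difference at 0.25. With quantile normalization the median H minus L difference was -0.003. Without replicate 3 of C2, 837 were called in pair C, against 1329.

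At the 2106 probe sets called between H and L, the reselected pairs had the sign of the founders at 78.8% (A), 75.5% (B), 75.4% (C) and 87.3% (D), a mean of 79.2% (SD 5.6, n = 4 pairs), and the CA pair at 50.3%. Pair A was called with the founder sign at 753 and against it at 52, pair B at 665 and 46, pair C at 641 and 63, pair D at 701 and 12, and CA at 295 and 297. The founder sign was called in at least 1 reselected pair at 1340 probe sets and in all 4 at 175, while 700 were called in none. Across probe sets, which are not independent, Pearson r with the founder difference was 0.47, 0.48, 0.45 and 0.62 for A to D (Spearman rho 0.37, 0.33, 0.30 and 0.46), and rho was -0.03 for CA.

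**Figure D2:**
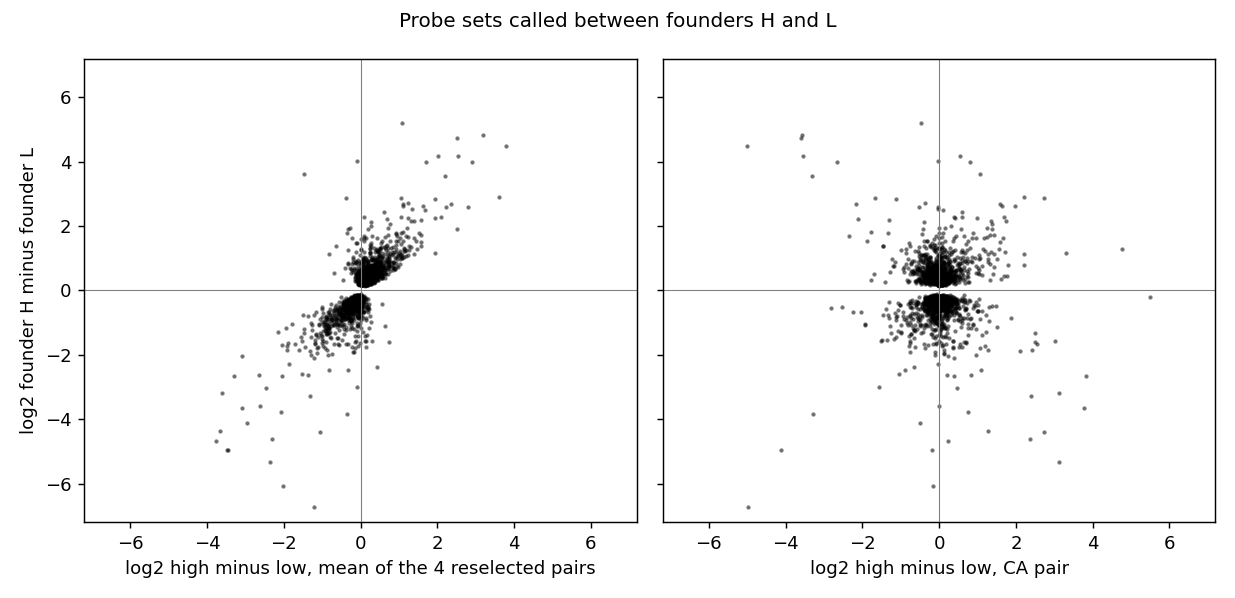
Log2 founder H minus founder L (y) against log2 high minus low (x), as the mean of the 4 reselected pairs on the left and in the CA pair on the right, with 1 point for each of the 2106 probe sets called between H and L. The mean share with the founder sign was 79.2% over the reselected pairs, and the share was 50.3% in CA.

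On a scale with L at 0 and H at 1, the high reselected lines lay at 0.629 ± 0.0604 and the low ones at 0.128 ± 0.0143 (mean ± SD, n = 4 lines each). The difference of 0.501 had an exact permutation p = 0.0286 and a sign-flip p = 0.125, two-sided, each the smallest this design allows. The lines lay at 0.658 and 0.114 (A1, A2), 0.593 and 0.148 (B1, B2), 0.567 and 0.127 (C1, C2), and 0.700 and 0.125 (D1, D2), and the CA lines at 0.376 and 0.365. With each array centred on its median the difference was 0.202 (exact permutation p = 0.229). At 67 probe sets at least 4-fold apart between founders, 52.2% of levels in high lines lay within 0.25 of H on this scale, 15.7% within 0.25 of L and 23.9% between these windows, against 8.2%, 69.4% and 17.2% in low lines. These positions and shares set reselected arrays from 1 run of title numbers against founder arrays from the other, where 10th percentile signals were 22.2 to 33.9 and 27 to 53.51. A shift between runs would move them, whereas high and low reselected lines share a run.

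**Figure D3:**
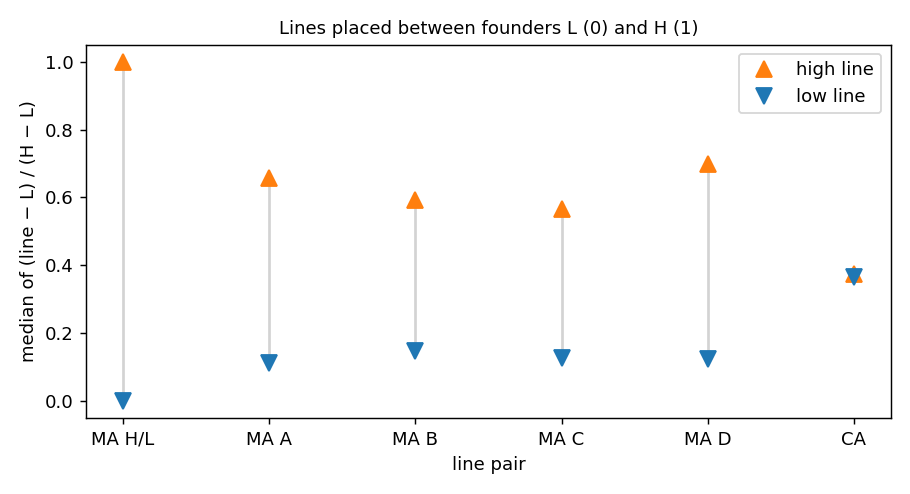
Median position of each line (y) between L at 0 and H at 1, by pair (x). High reselected lines lay from 0.567 to 0.700 and low ones from 0.114 to 0.148.

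In the CA pair, the zinc finger gene unk rose by 6.05 ± 0.49 (± SE, n = 3 arrays per line, adjusted p = 4.26e-11), from 74.07 ± 65.3 to 3020 ± 204, although its second probe set gave -1.53. Pp1-87B, a catalytic subunit of protein phosphatase 1, rose by 5.50 ± 0.07 (adjusted p = 2.86e-33), from 729.9 ± 68.4 to 33000 ± 1520. The general transcription factor gene TfIIA-L rose by 3.32 ± 0.06 (adjusted p = 1.14e-27), from 1441 ± 72.1 to 14350 ± 992. Ir76a fell by 5.00 ± 0.48 (adjusted p = 2.51e-09), from 2259 ± 365 to 70.67 ± 12.9. RhoGDI fell by 4.54 ± 0.10 (adjusted p = 1.86e-26), from 33400 ± 676 to 1464 ± 400. The signals of unk in the low line and Ir76a in the high line lay far under the filter level of 259.72, with no detection calls to show that they were above background. With a pseudocount of the 10th percentile of all signals, the differences were 5.12 and -4.51. In MA high and low lines, unk averaged 3818 and 3103, and Pp1-87B 35690 and 38430. TfIIA-L averaged 14760 and 15090 there, and RhoGDI 43220 and 44610. Thus CA low stood apart from the other lines for unk, Pp1-87B and TfIIA-L, and CA high for RhoGDI. The last 3 genes had no second tested probe set, so sequence differences under the probes could not be told apart from changed expression.

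Also higher in the CA high line were CG15628 (5.00 ± 0.42), CG33099 (4.77 ± 0.42), CG8539 (3.83 ± 0.58), CG17364 (3.83 ± 0.41), the adenylate kinase gene Adk3 (3.24 ± 0.30), CG1894 (3.13 ± 0.44), Cyp6a17 (3.12 ± 0.56, adjusted p = 9.73e-05), the serine protease gene grass (3.03 ± 0.26) and CG7650 (2.87 ± 0.24, second probe set 2.20). Lower were Rnf11 (-4.98 ± 0.35, second probe set -3.29), CG32284 (-4.97 ± 0.31), Spn47C (-3.59 ± 0.63), the sugar transporter gene sut2 (-3.31 ± 0.27), CG7173 (-2.81 ± 0.16), CG15211 (-2.57 ± 0.42), Wdr33 (-2.54 ± 0.10), CG14314 (-2.38 ± 0.24) and CG7906 (-2.38 ± 0.47). In all, 1597 probe sets were called, 748 higher and 849 lower, and the higher share moved from 46.8% to 62.7% with each array centred on its median. Errors are SE from the model of all 36 arrays, which pools the spread between arrays over the lines. The line with less signal gave 37.47 ± 14 for CG33099, 55.6 ± 27.7 for Adk3, 79.9 ± 94.7 for CG15628 and 97.53 ± 68.4 for CG8539 in CA low (± SD), and 77.37 ± 84.8 for CG15211, 81.2 ± 43.5 for Rnf11 and 84.63 ± 51.1 for CG7906 in CA high. The 10th percentile of the CA arrays was 27 to 35.6, so these values may be background and their differences are not exact. With the pseudocount CG33099 gave 3.94, Adk3 2.63, CG15628 4.17, CG8539 3.30, CG15211 -1.94, Rnf11 -4.50 and CG7906 -1.93, all still called. Cyp6a17 and CG7650 in CA low, and Spn47C, CG32284, CG7173 and the second probe set of Rnf11 in CA high, also had mean signals under 259.72 (100.5 to 197.7).

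The CA difference was larger than the MA mean by 7 ± 0.64 for CG8539 (± SE, adjusted p = 4.72e-10), 6.65 ± 0.61 for Cyp6a17 (adjusted p = 6.34e-10), 6.09 ± 0.48 for CG1894, 5.75 ± 0.53 for unk and 5.61 ± 0.07 for Pp1-87B. It was smaller for Ir76a (-8.94 ± 0.53, adjusted p = 2.23e-14), Spn47C (-6.56 ± 0.69), sut2 (-5.78 ± 0.29), CG32284 (-4.73 ± 0.34), RhoGDI (-4.50 ± 0.11), CG32373 (-3.24 ± 0.17) and ltl (-3 ± 0.17). Hr3 differed by 2.94 ± 0.44 (adjusted p = 5.66e-06) and GstO3 by 1.75 ± 0.10. No difference passed for Marf1 (0.02 ± 0.34, adjusted p = 0.978), Mis12 (-0.08 ± 0.18, adjusted p = 0.821), pst (-0.10 ± 0.15, adjusted p = 0.711), Cyp310a1 (-0.19 ± 0.41, adjusted p = 0.803) or CG32017 (-1.26 ± 0.50, adjusted p = 0.0667). In the CA pair itself Marf1 gave 1.59, Mis12 1.26, pst -1.36, CG32017 2.20 (193.2 in CA high and 59.23 in CA low, both under 259.72) and Cyp310a1 1.42, the last not called without replicate 3 of the CA high line (adjusted p = 0.0753). These SE come from the spread between arrays and leave out that between MA pairs, whose SD was 2.56 for CG1894 (pair values from -5.33 to 0.69), 1.62 for sut2, 1.54 for Spn47C, 1.21 for Cyp6a17 and 1.01 for Ir76a. With each MA pair in turn set against the other 5 pairs in place of CA, 219 (D) to 793 (C) were called. Between CA and MA, 2136 probe sets were called, 1017 higher and 1119 lower, and the higher share moved from 47.6% to 68.2% with each array centred on its median.

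Of the 175 concordant MA probe sets, 75 (42.9%) were also called in CA, 39 with the same sign (14.8 expected) and 36 with the opposite sign (15 expected). Those higher in both numbered 26 (7.7 expected) and those lower in both 13 (7.1 expected). The two-sided Fisher p for the overlap was 4.96e-16, across probe sets that are not independent, and the two-sided sign test gave p = 0.818. The expected counts and the Fisher test also take calls in MA and CA as independent. Both came from 1 fit with a shared variance per probe set, so the excess cannot show that the populations changed the same genes. Of the 909 called over MA pairs, 278 were called in CA, 141 with the same and 137 with the opposite sign (77.3 and 77.4 expected).

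Among 14 hemocyte markers tested in MA, 8 fell, 0 rose and 6 did not pass (adjusted over the list alone, 9 fell and 1 rose). PPO1 (-1.75), eater (-1.53), crq (-1.24), PPO2 (-1.10) and Pxn (-0.98) fell. Of markers chosen after their values were seen, He (-0.78) and Hml (-0.53) fell, while NimC1 gave 0.27 and atilla 0.40. The list passed (adjusted p = 0.000135, median -0.557, mean below 0 in 5 of 5 pairs), but with an estimated correlation it had adjusted p = 0.971 (camera p = 0.0607 before adjustment). The passing value rests on the preset correlation of 0.01, whereas the markers had a mean correlation of 0.184 between arrays of a line. By fry, which tests whether a list's genes move on balance one way without comparing them with other genes, adjusted p = 0.0589. PPO1 was not called without any 1 of 6 arrays (largest adjusted p = 0.083), PPO2 of 4 (0.0745), eater of 15 (0.081) and Hml of 3 (0.111). Without the intensity trend PPO1, PPO2 and eater were not called (adjusted p = 0.0878, 0.0869 and 0.0866), whereas crq, Pxn and He kept their calls. Of 14 heat shock genes, 4 fell and 0 rose, led by Hsp68 (-1.29 ± 0.78, SD over 5 pairs), which lost its call without any 1 of 5 arrays (largest adjusted p = 0.0765), and DnaJ-1 (-0.32 ± 0.15, 3 arrays, 0.103). Hsc70-5 (-0.29 ± 0.20) and Hsp110 (-0.18 ± 0.09) each lost their calls without any 1 of 11 arrays (largest adjusted p = 0.0905 and 0.0686). That list passed with adjusted p = 0.0112 (median -0.116), but with an estimated correlation it had adjusted p = 0.971 (camera p = 0.133 before adjustment). The adjusted p was 0.143 by fry and 0.0651 without replicate 3 of line H. Hemocyte genes also stood in other lists: Pxn in the extracellular matrix list, ush (-0.23) in the wing and hinge list and srp, chosen after its value was seen (-0.58, adjusted p = 0.0511), in the fat body list.

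**Figure D4:**
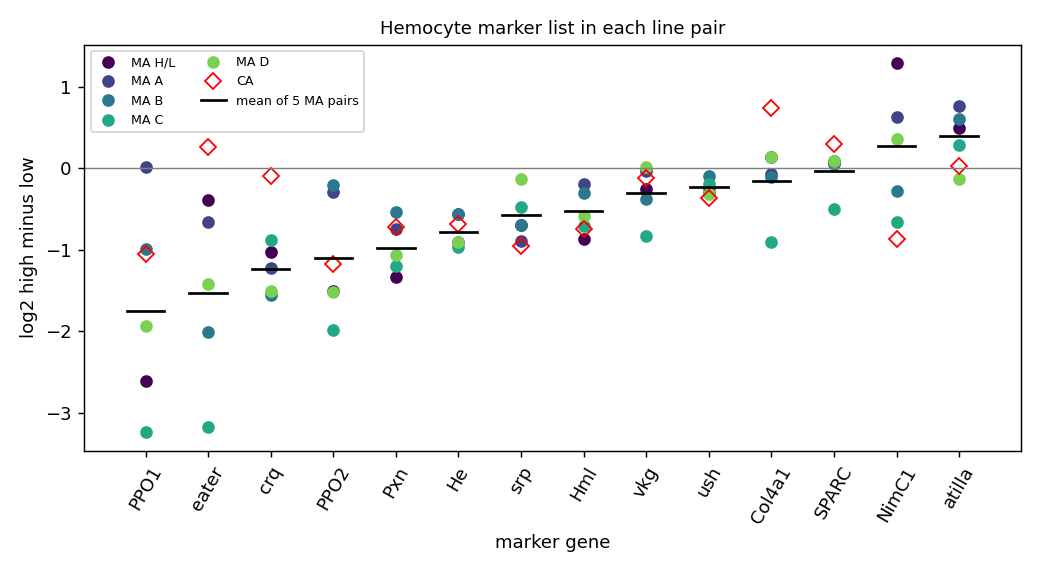
Log2 high minus low (y) of 14 hemocyte marker genes (x), with 1 dot per MA pair, a black bar for the mean of the 5 MA pairs and a red diamond for the CA pair. PPO1 had an MA mean of -1.75 and atilla 0.40.

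For the other lists in MA, the counts are higher and lower members among those tested, with the counts adjusted over the list alone and the camera adjusted p in brackets, and the named members with SD over 5 pairs. Hedgehog genes gave 2 and 0 of 14 (2 and 1, adjusted p = 0.954). Named were inv (0.27 ± 0.09) and smo (0.18 ± 0.06). Dpp genes gave 1 and 1 of 18 (2 and 1, adjusted p = 0.819). Named were Mad (0.36 ± 0.18) and wit (-0.17 ± 0.06). Wingless genes gave 1 and 1 of 12 (1 and 2, adjusted p = 0.958). Named were wls (0.33 ± 0.22) and nkd (-0.35 ± 0.09). Notch genes gave 0 and 0 of 20 (0 and 0, adjusted p = 0.845). EGFR genes gave 0 and 0 of 17 (0 and 0, adjusted p = 0.958). Vein genes gave 0 and 0 of 20 (0 and 0, adjusted p = 0.814). Wing and hinge genes gave 1 and 2 of 27 (1 and 3, adjusted p = 0.958). Named were Doc2 (0.30 ± 0.06), ush (-0.23 ± 0.09) and pnr (-0.42 ± 0.20). Hippo and planar polarity genes gave 4 and 3 of 28 (5 and 4, adjusted p = 0.958). Named were fj (0.44 ± 0.24), kibra (-0.47 ± 0.23), l(2)gl (-0.48 ± 0.11) and in (-0.68 ± 0.29). Leaving out 1 array ended the calls of smo (2 arrays, largest adjusted p = 0.0509), wit (9, 0.0755), wls (3, 0.0742) and ush (3, 0.0716), and of inv without replicate 1 of A2 (0.0594). The calls of Mad, Doc2 and fj were lost in at least 1 of 2 settings, without the intensity trend or with each array centred on its median.

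Errors of further MA lists are SD over 5 pairs. Insulin genes gave 2 and 2 of 15 (2 and 2, adjusted p = 0.958). Named were S6k (0.51 ± 0.29), Pdk1 (0.22 ± 0.12), melt (-0.35 ± 0.07) and ImpL2 (-0.78 ± 0.42). JNK and apoptosis genes gave 0 and 1 of 19 (0 and 1, adjusted p = 0.958). Named was Traf4 (-0.31 ± 0.10). Cell cycle genes gave 1 and 0 of 32 (0 and 0, adjusted p = 0.0665). Named was fzy (0.17 ± 0.07). Cytosolic ribosomal genes gave 0 and 0 of 32 (0 and 0, adjusted p = 0.958). Mitochondrial ribosomal genes gave 5 and 4 of 71 (5 and 7, adjusted p = 0.256). Named were mRpS6 (0.43 ± 0.13), mRpL21 (0.30 ± 0.09), mRpL27 (-0.31 ± 0.10) and mRpL42 (-0.46 ± 0.24). Oxidative phosphorylation genes gave 0 and 0 of 61 (0 and 0, adjusted p = 0.958). Ecdysone genes gave 0 and 4 of 23 (0 and 4, adjusted p = 0.958). Named were Cth (-0.27 ± 0.13), Sb (-0.49 ± 0.25), ImpL2 (-0.78 ± 0.42) and Hr3 (-1.66 ± 0.79). Dosage compensation genes gave 1 and 1 of 11 (2 and 1, adjusted p = 0.958). Named were msl-3 (2.00 ± 0.20) and msl-1 (-0.23 ± 0.08). With 1 array left out, calls were lost for Pdk1 (5 arrays, largest adjusted p = 0.144) and fzy (20, 0.0907), and for S6k without replicate 1 of C2 (0.0599). The calls of mRpL21, Cth and msl-1 were lost in at least 1 of 2 settings, without the intensity trend or with each array centred on its median. The cell cycle list passed without any 1 of 5 arrays (smallest adjusted p = 0.0297), but with all arrays and an estimated correlation it had adjusted p = 0.971.

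The cuticle, matrix, detoxification and immune lists in MA follow, with SD over 5 pairs. Cuticle genes gave 6 and 3 of 61 (9 and 4, adjusted p = 0.267). Named were Cpr65Ec (1.09 ± 0.08), Gasp (1.07 ± 0.32), Cpr72Eb (0.81 ± 0.39) and serp (-0.80 ± 0.31). Matrix genes gave 3 and 4 of 29 (3 and 4, adjusted p = 0.813). Named were mew (0.30 ± 0.08), Sb (-0.49 ± 0.25), rhea (-0.57 ± 0.11) and Pxn (-0.98 ± 0.33). P450 genes gave 1 and 1 of 31 (1 and 1, adjusted p = 0.958). Named were Cyp310a1 (1.61 ± 0.53) and Cyp6a17 (-3.53 ± 1.21). Glutathione S-transferase genes gave 2 and 4 of 25 (4 and 8, adjusted p = 0.0658). Named were GstE11 (2.87 ± 1.97), se (1.58 ± 0.74), GstE3 (-0.93 ± 0.29) and GstO3 (-1.84 ± 0.21). Immune genes gave 3 and 1 of 18 (3 and 1, adjusted p = 0.958). Named were GNBP2 (1.11 ± 0.16), Def (1.09 ± 0.60), GNBP3 (0.44 ± 0.14) and dl (-0.34 ± 0.11). Leaving out 1 array ended the calls of GstE11 without replicate 3 of B2 (0.0525) and Def without replicate 2 of C2 (0.0516). The call of mew was lost in at least 1 of 2 settings, without the intensity trend or with each array centred on its median. The glutathione S-transferase list passed without any 1 of 7 arrays (smallest adjusted p = 0.0406) and without a filter (adjusted p = 0.0277), but with all arrays, the filter and an estimated correlation it had adjusted p = 0.971.

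For tissue markers in MA, errors are SD over 5 pairs. Myoblast genes gave 0 and 0 of 11 (0 and 0, adjusted p = 0.958). Tracheal genes gave 1 and 1 of 11 (2 and 3, adjusted p = 0.958). Named were Gasp (1.07 ± 0.32) and serp (-0.80 ± 0.31). Fat body genes gave 0 and 0 of 9 (1 and 1, adjusted p = 0.958). Salivary gland genes gave 0 and 0 of 5 (0 and 0, adjusted p = 0.958). Muscle genes gave 0 and 0 of 9 (0 and 0, adjusted p = 0.907). Other disc genes gave 2 and 0 of 11 (2 and 0, adjusted p = 0.256). Named were eya (0.53 ± 0.32) and chp (0.39 ± 0.15). Neuronal genes gave 1 and 1 of 10 (1 and 2, adjusted p = 0.958). Named were Brd (0.59 ± 0.35) and Tom (-0.23 ± 0.08). Testis genes gave 0 and 0 of 6 (0 and 0, adjusted p = 0.897). With 1 array left out, calls were lost for eya (2 arrays, largest adjusted p = 0.0607) and chp (2, 0.0549). The calls of Brd and Tom were lost in at least 1 of 2 settings, without the intensity trend or with each array centred on its median. Median, mean and test differed in sign for the Wingless, wing and hinge, insulin, oxidative phosphorylation, ecdysone, JNK, trachea, neuron and dosage lists. No list held its call with an estimated correlation, where every MA adjusted p was 0.971.

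A probe set other than the brightest, which stood for its gene in the lists, was called for some list genes, given here after their values were seen. In MA, 3 such genes had a concordant one: ImpE1 in the ecdysone list (1.31 ± 0.25, brightest -0.30), Mkp3 in the EGFR list (1.04 ± 0.12, brightest -0.14) and mRpS11 among mitochondrial ribosomal genes (0.88 ± 0.07, brightest -0.15), with SD over 5 pairs. Their adjusted p over line pairs were 0.0006445, 0.0006445 and 0.0001236, and none of the 3 brightest was called. Others called over line pairs were those of Antp (0.35), mys (0.39), GstO2 (-0.27) and RpL3 (-0.29). In CA these were Mkp3 (0.47), RpS30 (0.71), trol (0.42), ND-ACP (0.32), GstO2 (-0.61), Cht6 (-0.64), mirr (-0.78), Cyp18a1 (-0.86) and nub (-0.89).

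In the CA pair, ptc, the Hedgehog receptor gene, fell, and list members are given with SE from the model of all 36 arrays. Hedgehog genes gave 0 and 3 of 14 (0 and 3, adjusted p = 0.363). Named were kn (-0.43 ± 0.11), rasp (-0.62 ± 0.09) and ptc (-0.72 ± 0.12). Dpp genes gave 1 and 1 of 18 (1 and 1, adjusted p = 0.876). Named were Dad (0.81 ± 0.09) and wit (-0.37 ± 0.07). Wingless genes gave 0 and 1 of 12 (0 and 1, adjusted p = 0.639). Named was nkd (-0.30 ± 0.09). Notch genes gave 1 and 3 of 20 (2 and 3, adjusted p = 0.906). Named were H (0.69 ± 0.15), E(spl)m2-BFM (-0.25 ± 0.08), E(spl)m4-BFM (-0.53 ± 0.10) and E(spl)m7-HLH (-0.55 ± 0.12). Delta, written Dl in the Notch and vein lists, was not matched to its symbol and entered neither list. Of its 2 tested probe sets, given after their values were seen, the brighter was called at -1.77 and the other gave -0.55. EGFR genes gave 1 and 1 of 17 (1 and 1, adjusted p = 0.876). Named were Krn (0.29 ± 0.10) and S (-0.35 ± 0.08). Vein genes gave 1 and 3 of 20 (2 and 4, adjusted p = 0.876). Named were shf (0.22 ± 0.08), Dys (-0.30 ± 0.10), ara (-0.31 ± 0.09) and Dg (-0.81 ± 0.20). Wing and hinge genes gave 0 and 5 of 27 (0 and 5, adjusted p = 0.113). Named were Chi (-0.35 ± 0.07), ush (-0.37 ± 0.12), pdm2 (-0.37 ± 0.08) and drm (-0.76 ± 0.11). Hippo and planar polarity genes gave 2 and 8 of 28 (3 and 8, adjusted p = 0.805). Named were dco (0.58 ± 0.09), dgo (-0.44 ± 0.10), Fbxl7 (-0.44 ± 0.14) and fj (-0.50 ± 0.13). Calls in CA were lost with 1 array left out for nkd (4 arrays, largest adjusted p = 0.0973), E(spl)m2-BFM (6, 0.182), Krn (4, 0.138), shf (6, 0.141), Dys (5, 0.136), ara (2, 0.0918), ush (5, 0.152) and Fbxl7 (2, 0.176), and for fj without replicate 1 of the CA low line (0.0507). The calls of kn, wit, S, Chi, pdm2 and dgo were lost in at least 1 of 2 settings, without the intensity trend or with each array centred on its median. The wing and hinge list passed without a filter (adjusted p = 0.0153), with probe sets from the 75th percentile (adjusted p = 0.037) and without replicate 3 of the CA high line (adjusted p = 0.0446). In the main setting with an estimated correlation it had adjusted p = 0.749.

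Errors of further CA lists are SE from the model of all 36 arrays. Insulin genes gave 1 and 0 of 15 (1 and 0, adjusted p = 0.591). Named was eIF4E1 (0.42 ± 0.06). JNK and apoptosis genes gave 2 and 3 of 19 (4 and 3, adjusted p = 0.947). Named were p53 (0.29 ± 0.10), Traf4 (-0.39 ± 0.11), Dronc (-0.47 ± 0.09) and msn (-0.57 ± 0.18). Cell cycle genes gave 1 and 0 of 32 (0 and 0, adjusted p = 0.363). Named was PolA1 (0.23 ± 0.08). Cytosolic ribosomal genes gave 0 and 0 of 32 (0 and 0, adjusted p = 0.363). Mitochondrial ribosomal genes gave 3 and 5 of 71 (2 and 3, adjusted p = 0.823). Named were mRpS26 (0.84 ± 0.14), mRpL48 (-0.30 ± 0.10), mRpL54 (-0.34 ± 0.11) and mRpS5 (-0.45 ± 0.09). Oxidative phosphorylation genes gave 5 and 4 of 61 (5 and 4, adjusted p = 0.363). Named were COX5B (0.79 ± 0.08), ND-13B (0.69 ± 0.10), ND-SGDH (-0.57 ± 0.08) and ATPsynepsilonL (-0.77 ± 0.17). Ecdysone genes gave 5 and 3 of 23 (7 and 3, adjusted p = 0.546). Named were Hr3 (1.28 ± 0.40), Blimp-1 (0.67 ± 0.23), Cht7 (0.67 ± 0.21) and Eip78C (-0.50 ± 0.13). Dosage compensation genes gave 2 and 2 of 11 (2 and 2, adjusted p = 0.876). Named were msl-3 (0.99 ± 0.18), tra (0.44 ± 0.11), mle (-0.30 ± 0.09) and msl-2 (-0.81 ± 0.24). Calls in CA were lost with 1 array left out for p53 (4 arrays, largest adjusted p = 0.165), msn (5, 0.0923), PolA1 (4, 0.151), mRpL48 (3, 0.19), mRpL54 (2, 0.152), Hr3 (3, 0.109), Blimp-1 (4, 0.235), Cht7 (4, 0.142), mle (4, 0.106) and msl-2 (3, 0.0688), and for Eip78C without replicate 3 of the CA low line (0.0596). The call of Traf4 was lost in at least 1 of 2 settings, without the intensity trend or with each array centred on its median.

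The cuticle, matrix, detoxification, immune and heat shock lists in CA follow, with SE from the model of all 36 arrays. Cuticle genes gave 10 and 5 of 61 (10 and 5, adjusted p = 0.591). Named were Cpr51A (1.55 ± 0.30), Cpr72Ea (1.15 ± 0.30), Cht5 (1.02 ± 0.12) and Cpr78E (0.97 ± 0.19). Matrix genes gave 5 and 0 of 29 (5 and 3, adjusted p = 0.619). Named were Col4a1 (0.74 ± 0.20), tyn (0.55 ± 0.14), LanB1 (0.39 ± 0.08) and SPARC (0.30 ± 0.10). P450 genes gave 3 and 0 of 31 (2 and 0, adjusted p = 0.619). Named were Cyp6a17 (3.12 ± 0.56), Cyp310a1 (1.42 ± 0.38) and Cyp6v1 (0.26 ± 0.09). Glutathione S-transferase genes gave 6 and 2 of 25 (6 and 3, adjusted p = 0.363). Named were Mgstl (1.77 ± 0.08), GstE1 (1.42 ± 0.42), GstE13 (0.53 ± 0.08) and GstD3 (-1.30 ± 0.11). Immune genes gave 3 and 1 of 18 (4 and 1, adjusted p = 0.713). Named were GNBP2 (0.85 ± 0.15), GNBP3 (0.39 ± 0.07), cact (0.30 ± 0.10) and Rel (-0.27 ± 0.10). Heat shock genes gave 2 and 0 of 14 (2 and 0, adjusted p = 0.113). Named were Hsp26 (0.77 ± 0.18) and Hsp110 (0.61 ± 0.05). Calls in CA were lost with 1 array left out for SPARC (4 arrays, largest adjusted p = 0.119), Cyp6v1 (21, 0.144), GstE1 (2, 0.0644), cact (4, 0.137) and Rel (30, 0.35), and for Cpr72Ea without replicate 3 of the CA low line (0.108), Col4a1 without replicate 3 of the CA high line (0.0551) and Cyp310a1 without replicate 3 of the CA high line (0.0753). The oxidative phosphorylation and heat shock lists passed without replicate 3 of the CA high line (adjusted p = 0.0446 each), but with all arrays and an estimated correlation they had adjusted p = 0.775 and 0.749.

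For tissue markers in CA, errors are SE from the model of all 36 arrays. Myoblast genes gave 3 and 1 of 11 (3 and 1, adjusted p = 0.619). Named were sns (0.64 ± 0.17), hbs (0.36 ± 0.12), rols (0.32 ± 0.09) and htl (-0.60 ± 0.10). Tracheal genes gave 1 and 1 of 11 (1 and 1, adjusted p = 0.906). Named were Gasp (0.94 ± 0.13) and serp (-0.54 ± 0.12). Fat body genes gave 1 and 3 of 9 (2 and 4, adjusted p = 0.823). Named were FASN1 (1.11 ± 0.17), Mtp (-0.66 ± 0.09), fat-spondin (-0.73 ± 0.24) and srp (-0.95 ± 0.31). Salivary gland genes gave 0 and 0 of 5 (0 and 0, adjusted p = 0.93). Muscle genes gave 0 and 1 of 9 (0 and 1, adjusted p = 0.656). Named was Act87E (-1.96 ± 0.14). Other disc genes gave 0 and 2 of 11 (0 and 2, adjusted p = 0.619). Named were chp (-0.44 ± 0.14) and eya (-0.88 ± 0.25). Neuronal genes gave 0 and 2 of 10 (0 and 2, adjusted p = 0.591). Named were sc (-0.30 ± 0.10) and Brd (-0.30 ± 0.10). Testis genes gave 0 and 0 of 6 (0 and 0, adjusted p = 0.876). Hemocyte genes gave 2 and 4 of 14 (2 and 7, adjusted p = 0.387). Named were Col4a1 (0.74 ± 0.20), NimC1 (-0.87 ± 0.22), srp (-0.95 ± 0.31) and PPO2 (-1.18 ± 0.42). Calls in CA were lost with 1 array left out for hbs (6 arrays, largest adjusted p = 0.151), rols (3, 0.0857), fat-spondin (4, 0.14), srp (4, 0.13), chp (4, 0.122), eya (2, 0.0732), sc (4, 0.217), Brd (4, 0.153) and PPO2 (25, 0.167), and for sns without replicate 3 of the CA low line (0.0528) and Col4a1 without replicate 3 of the CA high line (0.0551). Median, mean and test differed in sign for the Dpp, matrix, JNK, immune and muscle lists. By fry, adjusted p was 0.000114 for Hedgehog, 0.000429 for wing and hinge, 0.0331 for glutathione S-transferases, 0.00172 for heat shock and 2e-04 for muscle, but with an estimated correlation every CA adjusted p was 0.749 or above.

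Concordant MA genes lay beside each other more often than random genes: 16.2% of 148 genes had a concordant gene as the next tested gene, against a mean of 3.9% and a highest of 12.8% in 1000 random draws (one-sided permutation p = 0.000999, the smallest possible). Runs join concordant genes at most 5 places apart. The longest, with genes chosen after their values were seen, held Mis12 (1.34), CG9953 (0.25), Mp (-0.78), Cpr65Ec (1.09) and msl-3 (2.00) within 9 places on chromosome arm 3L. With each array centred on its median CG9953 was not called over line pairs (adjusted p = 0.148). There were 2 runs of 4 genes, 4 of 3 and 22 of 2, and 79 genes had no concordant gene within 5 places (46.6% of the 148 had one). The shares for single pairs were 36.8% in A (30.1% at random, permutation p = 0.000999), 36.6% in B (25.3%, permutation p = 0.000999), 32.8% in D (20.6%, permutation p = 0.000999), 32.4% in C (27.6%, permutation p = 0.003), 39.0% in CA (33.9%, permutation p = 0.002) and 44.8% between H and L (42.8%, permutation p = 0.0719). Within 5 places, pairs A (permutation p = 0.207), C (permutation p = 0.0749), CA (permutation p = 0.234) and H against L (permutation p = 0.299) did not pass.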

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

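The tests on second probe sets, on neighbours with CG numbers and by regrouping samples were chosen after the result was seen, and the other tests on gene order and those on hemocytes before. In 5 of 70 groups of lines tested for 1 line apart from the rest, a line stood apart, where 3.5 are expected by chance (about 1 in 20). The mean log2 signal of CG32017 was 10.54 in B1 (other high lines 11.94 to 12.26), and that of Cyp6a17 was 7.12 in D2 (other low lines 10.28 to 10.92). CG15822 was at 10.33 in D1 (others 7.05 to 7.88), Ptr at 5.75 in B1 (7.54 to 7.75) and CG31522 at 11.8 in C1 (10.88 to 11.08). No line was left out for this.

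The CA and MA differences differed at 2136 probe sets. The largest were 7 for CG8539, 6.65 for Cyp6a17, 6.09 for CG1894, 5.75 for unk, 5.61 for Pp1-87B, -8.94 for Ir76a, -6.56 for Spn47C, -5.78 for sut2, -4.73 for CG32284 and -4.50 for RhoGDI (log2, n = 3 arrays per line, limma). The CA population has 1 pair, so these hold for that pair, and the test leaves out the spread between MA pairs (SD 2.56 for CG1894). With each MA pair in the place of CA, 219 to 793 were called. Signals of unk (74.07 in CA low) and Ir76a (70.67 in CA high) may be background, and with the pseudocount their differences were 4.82 and -8.03. Signals under 259.72 were also found for CG8539 (97.53) and Cyp6a17 (122) in CA low, and Spn47C (100.5) and CG32284 (196.5) in CA high. With the pseudocount these 4 gave 6.21, 5.92, -6 and -4.55.

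Among the concordant genes, 12 pairs were adjacent. Families were judged only by symbols that share their letters, which left out 0 of these pairs and kept the share at 16.2%, so the bound written for this test was met without testing it. A symbol made of CG and a number tells no family, and 3 pairs had one on both sides and 7 on at least 1 side. Leaving out such neighbours gave 12.2% (highest of 1000 random draws under the same rule 10.8%) and 6.8% (8.1%). Neighbours from 1 family cannot be told apart from other causes here, since no sequences were compared. Neighbouring founder-called genes tended to take H-like or L-like levels in the same reselected lines, with a mean correlation of 0.236. The highest mean among 100 sets of random gene pairs on different chromosomes was 0.067, and the mean was 0.018 at the largest distance tested. This covered all 1691 founder-called genes, with levels centred within the high and within the low lines. It shows linkage within a direction, but the centring removes the high minus low difference that makes a gene concordant. Whether linked founder haplotypes carry some concordant genes along therefore stays open. Whether selection or drift fixed such haplotypes, and which gene of a run mattered, was not tested and stays open.

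In genes with a second tested probe set, the median ratio of its difference to that of the lead was -0.02 in MA (95% interval -0.185 to 0.193, 13 genes) and 0.055 in CA (-0.011 to 0.172, 35 genes). The ratio was under 0.25 in 10 of 13 MA and 28 of 35 CA genes, and over 0.5 in 2 and 3. The sign was opposite in 8 and 12. Sequence differences under the probes could produce this, and so could changes in 1 isoform, while choosing the larger difference as lead favours disagreement. msl-3 (ratio 0.728) and regucalcin (0.67) in MA, and CG7650 (0.767), CG5326 (0.673) and Rnf11 (0.661) in CA, had a second probe set with a similar difference.

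The 14 markers varied together between arrays of a line (mean correlation 0.184, against a highest of 0.083 in 100 random sets), so different amounts of hemocytes on the discs may have moved them. The prediction written for separate alleles of each marker was wrong, because arrays of 1 line share alleles and their covariation cannot exclude allele differences between lines. Whether such amounts reflect the animals or the cleaning of the discs was not tested and stays open.

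Among 100 drawn splits of the 10 MA lines into 5 and 5, fitted without the line pair, 1, the real one, gave as many calls (829, highest other 24). This split would exclude chance only for unpaired and independent lines. The labels tie the lines of a letter to 1 hybrid population, and H and L are the parents of the rest, so it cannot exclude chance here. For the rest the splits were too few for a share below 0.05: calls over MA pairs with the pairs kept 909 and 1 over 16 arrangements, concordant calls 175 and 9 over 16 arrangements, CA against MA 2136 and 793 over 6, and single pairs 1979 and 0 (H and L), 1333 and 0 (A), 711 and 0 (B), 671 and 2 (C), 717 and 1 (D) and 1667 and 0 (CA) over 10.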

How the results depend on the processing

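With probe sets kept from the 75th percentile, calls numbered 770 in pair B, 1037 in CA, 570 over MA pairs, 113 concordant, 121 concordant in the 4 reselected pairs and 1373 for CA against MA, and 24 overlapped CA with the same sign. With each array centred on its median, they were 729 in A, 713 in B, 745 in C, 529 in D, 969 in CA, 106 concordant and 115 in the 4 reselected pairs, the overlap was 21 and 17, the founder sign held at 72.6% and the position difference was 0.202 (exact permutation p = 0.229). At 1.5-fold or more, calls were 749 between H and L, 535 in A, 530 in B, 517 in C, 411 in D and 634 in CA. Fitted alone, pair B gave 711 and pair C 671. Fewer probe sets tested or a stricter threshold lowers such counts by construction. Centring used the median of all 18769 probe sets, before the filter. H arrays had medians of 365.4 to 430.1 and L arrays 311 to 355.9, so centring lowered H against L at every probe set. The median H minus L difference was -0.201 with centring and 0.036 without. It was 0.118 without a filter, -0.012 from the 75th percentile and -0.003 with quantile normalization, so the offset lay mostly in dim probe sets. For the other pairs the cause was not tested.

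Over MA pairs, arrays with the line as a random block gave 1929 calls. Leaving out 1 pair gave 369 (without H and L) to 859, and leaving out 1 array up to 1001 (without replicate 3 of A2). Concordant calls ranged from 154 to 267, the latter without pair C, and pair C ranged from 837 (without replicate 3 of C2) to 1441. At an adjusted p of 0.01 there were 104 concordant, 113 in the 4 reselected pairs and an overlap of 21 and 15, and at 0.1 there were 220 and 239. CA against the H and L pair alone gave 1969 and against the reselected pairs 1958.

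The heat shock list in MA had adjusted p = 0.971 with an estimated correlation, 0.143 by fry and 0.00315 to 0.0651 with 1 array left out, the largest without replicate 3 of H. The hemocyte list had 0.971, 0.0589 and 3.72e-05 to 0.000727, and gave no value from the 75th percentile, with fewer than 5 members. The hemocyte markers had a mean correlation of 0.184 between arrays of a line, above the preset 0.01. The main adjusted p of that list therefore took its members as more independent than they were between arrays. For the other changes of the lists the cause was not tested. Neighbours within 5 places were 84.2% in A, 81.7% in C and 87.9% in CA (permutation p = 0.207, 0.0749 and 0.234).

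Arrays with the same replicate number in different lines had a mean correlation of deviations of 0.0188, against -0.00935 for other numbers, and 3 of 18 matched pairs passed 0.1 (-0.0642 to 0.188). With the number as a block, calls were 2182 between H and L, 1568, 1239, 1421 and 1003 in A to D, 1645 in CA, 190 concordant, 204 in the 4 reselected pairs, 2185 for CA against MA and an overlap of 44 and 39. The calls of Blimp-1 (adjusted p = 0.0509) and Cyp6v1 (0.0527) in CA were lost.

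Of 242 named-gene results, 27 were lost without a filter, 4 with quantile normalization, 47 with median centring and 25 without the trend, and 0 turned direction. With the pseudocount 0 were lost. With 1 array left out, 301 of 8711 gene results were lost and 5 gained, and 1 of 2232 list results was lost and 15 gained. In MA the glutathione S-transferase list passed in 7 of these (smallest adjusted p = 0.0406) and without a filter (0.0277), and the cell cycle list in 5 (smallest 0.0297). In CA the wing and hinge, oxidative phosphorylation and heat shock lists passed without replicate 3 of the high line (0.0446), and the first also without a filter (0.0153) and from the 75th percentile (0.037). In the main setting with an estimated correlation none of these 5 passed (0.971 in MA, 0.749 or above in CA).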

Other observations

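The longest run of concordant genes of the MA lines lay within 9 places on chromosome arm 3L, with Mis12 at 1.34, CG9953 at 0.25, Mp at -0.78, Cpr65Ec at 1.09 and msl-3 at 2.00. CG9953 was not called over line pairs with each array centred on its median (adjusted p = 0.148). Ir76a, Spn47C, Cyp6a17 and CG8539 were among the largest differences in both populations, with opposite signs: 3.93 and -5.00, 2.97 and -3.59, -3.53 and 3.12, and -3.17 and 3.83 in MA and CA.

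At the largest founder differences, with L at 0 and H at 1, 23.9% of levels in high lines and 17.2% in low lines lay more than 0.25 from both founders and between them. That window is a choice, and founders and reselected lines lie in separate runs of title numbers. The H arrays had the highest medians of all arrays, 365.4 to 430.1.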
